A study of Mus musculus with 47 samples.

How the data were processed

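RNA from mouse intestinal tissue and from intestinal organoids was sequenced as single reads on an Illumina Genome Analyzer IIx after ribosomal RNA depletion with RiboMinus. The 39 tissue libraries cover wild-type mucosa, uninvolved mucosa of Apc Min mice (Min mucosa) and adenomas of Apc Min mice. The Min allele of Apc, a tumour suppressor of the Wnt pathway, induces intestinal adenomas. The backgrounds are C57BL/6 (B6), the consomic strain that carries chromosome 5 of PWD/Ph on C57BL/6 (C5), the cross of B6 and C5 (C5F1), the cross of B6 and PWD (B6xPWD), and PWD itself as wild-type mucosa only. The 8 organoid libraries are B6 and C5 cultures with or without 5-aza-cytidine (AZA), a drug that traps DNA methyltransferases.

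The values are raw read counts per gene symbol, deposited by the authors in a table for all libraries. According to the labels, reads were aligned with BWA to mm10 and counted with HTSeq; versions, gene annotation and the strand setting were not given. The table holds whole numbers for 24062 gene symbols and 5 HTSeq summary categories for reads without a unique gene. The summary categories made up 40.7 to 53.9% of a tissue library's total and 46.4 to 63.5% of an organoid library's total, and they were left out. No other normalisation was found in the values. Gene symbols were matched to the RefSeq annotation of the same genome build for chromosome and position. By current symbol 22550 matched, by synonym 1352, and 160 had no match and carry no position.

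Counts assigned to genes ranged from 2726505 to 20070696 per tissue library (median 5831947) and from 4389898 to 8373764 per organoid library (median 6386046). The ribosomal precursor Rn45s took 16.4 to 72.7% of these counts in tissue and 0.760 to 1.61% in organoids. It was kept in the totals. No pair of libraries was a copy of another: over 43 pairs within groups the lowest chi-square per degree of freedom was 8.06.

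Each combination of background and tissue formed a group of 3 libraries, 13 groups in all, and each combination of background and treatment formed an organoid group of 2 libraries, 4 groups in all. Replicates are not stated to be separate animals or cultures, so p-values measure the spread between these samples. Sex is not given. Tissue and organoids were fitted apart with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr by group (minimum count 10, minimum total 15), which left 13657 genes in tissue and 13395 in organoids. Normalisation was TMM, and the test was the quasi-likelihood F-test on a model with 1 mean per group. Normalised CPM values carry the SD between libraries, and fitted log2 changes carry their SE and a prior count of 2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Where a group had no counts of a gene, the fold is a lower bound against 3 counts over the group. With 1 to 3 counts the ratio is of counts pooled over the libraries of each side and carries its exact 95% counting interval, so it can differ from the ratio of the mean CPM. Intervals and floors cover counting error only, since reads carry no molecular identifiers.

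The comparisons numbered 26. Adenoma was compared with Min mucosa in each background and as the mean of 4 backgrounds. Min mucosa was compared with wild-type mucosa in the same manner. Each background was compared with B6 in wild-type mucosa, and C5, C5F1 and B6xPWD also in adenoma. C5 and B6 were compared as the mean of 3 tissues, AZA and control organoids in each background and as a mean, and C5 and B6 in control organoids. Differences of the adenoma effect between backgrounds, and of the AZA effect between C5 and B6, were tested as interaction terms. For 7 main comparisons gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and again with an estimated correlation, and both p-values were adjusted over the lists.

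The 37 lists covered Wnt targets, stem cells, Paneth, goblet, enteroendocrine and tuft cells, enterocytes, cell cycle, fetal and regenerative genes, matrix remodelling, inflammation, BMP and Notch signalling, iron and HIF2 targets, interferon response, germline genes silenced by methylation, imprinted genes, DNA methylation enzymes, p53 targets, xenobiotic metabolism, antimicrobial genes, MHC class I and II, B and plasma cells, T cells, myeloid, mast and erythroid cells, fibroblasts, smooth muscle, endothelium, enteric nerves, pancreas, fat, and proximal intestine, distal ileum and colon. Some genes stand in more than 1 list. A list needed 3 tested members, so 35 lists were tested in tissue and 33 in organoids. Erythroid genes were testable in neither, germline genes only in organoids, and B and plasma cell, T cell and mast cell genes only in tissue.

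Groups, comparisons, lists, the test and the rule for named genes were fixed before the data were examined. The rule takes the 5 largest rises and the 5 largest falls among called genes with a mean of at least 5 CPM on the higher side and no overlap between the groups. It also takes the 2 members of each assigned list with the smallest p, the 3 genes with the smallest p for each difference of effects, and the 5 chromosome 5 genes with the smallest p between C5 and B6. Apc and Pla2g2a are always given. Some genes that the rule takes are not reported here. Predicted genes named Gm or Rik, immunoglobulin and T cell receptor segments, mitochondrial genes, small RNA families, Xist, Tsix and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were excluded from the largest changes. Other genes named below were chosen after their values were seen, except members of the lists. Genes that share reads with near-identical copies (the Defa, Bpifb, Ugt2b and Mcpt families, Rplp0, Rpl21, Gm15284 and Hist1h4j) have uncertain values.

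Replicate numbers were checked for pairing by correlating residuals of libraries with the same number. Adenoma and Min mucosa of the same background and number correlated at 0.107 or more in every one of the 12 pairs, above each other combination within the background (highest 0.147 in B6xPWD, where the lowest same-number value was 0.205). These numbers point to pairs, which the main fits ignore and the replicate block models. Alternatives planned in advance were RLE size factors, the Wald test of DESeq2 1.42.0, no filter on low counts, only the compared groups in the fit, the replicate block, and leaving out each library in turn. After the data were seen, 4 alternatives were added: counts without ribosomal genes, leaving out 3 wild-type libraries with Fabp6 below 100 CPM, leaving out 2 libraries with over 60% Rn45s, and the replicate block with adenoma and Min mucosa alone. Other splits of the libraries were counted for comparisons of at least 3 against 3 libraries. The procedure was tested on 100 4-fold and 100 2-fold changes planted in simulated data. It called 83 and 31 in C5 against B6 wild-type mucosa, with 3.39% of calls false. In C5 against B6 control organoids it called 75 and 43 (6.35% false). For Min against wild-type mucosa over 4 backgrounds it called 96 and 91 (4.10%), and for AZA 85 and 66 (6.21%). The rates are not shown to hold for the real libraries.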

Results

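The data describe gene expression in intestinal tissue of mice aged 15 to 19 weeks and in intestinal organoids, in backgrounds that differ in their share of the PWD genome. Wild-type mucosa was sampled in B6, C5F1, C5, B6xPWD and PWD, and Min mucosa and adenoma in the first 4 of these, with 3 libraries in each of the 13 groups. The organoid groups were B6 and C5, each as control and after AZA, with 2 libraries in each of the 4 groups. Gene counts per library ranged from 2726505 to 20070696 in tissue and from 4389898 to 8373764 in organoids. Positions refer to mm10, and changes given without a fold are on the log2 scale.

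The comparison of adenoma with Min mucosa asks which genes mark the tumour tissue across backgrounds. Wnt target genes were far higher in adenoma. Notum, a secreted inhibitor of Wnt on chromosome 11, averaged 52.7 ± 41.3 CPM (SD, n = 12) in adenoma and 0.49 ± 0.488 CPM (n = 12) in Min mucosa, a change of 6.77 ± 0.33 (SE, adjusted p = 8.59e-17). Prox1, a transcription factor induced by Wnt in intestinal tumours, rose 10.7-fold, from 5.09 ± 0.921 to 62.1 ± 36.4 CPM. Of 24 Wnt targets 23 rose and 1 was not called, among them Wif1 (5.61), Lef1 (3.48), Nkd1 (3.20), Lgr5 (0.99) and Axin2 (0.79). The camera adjusted p was 3.64e-19, and adjusted p = 0.00222 with an estimated correlation. Apc itself was at 140 ± 20.9 CPM in adenoma and 152 ± 19.96 CPM in Min mucosa, a change of -0.11 ± 0.09 (adjusted p = 0.332).

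The 5 largest rises were Anxa10, Bpifb5, Bpifb1, Gkn3 and T. Anxa10, an annexin of the stomach, rose 246-fold to 14.6 ± 8.88 CPM, and Gkn3, a gastrokine of the stomach, rose 204-fold to 37.4 ± 31.8 CPM. Brachyury (T), a mesoderm transcription factor, rose by a ratio of 437 (95% counting interval 78.0 to 17273). Bpifb5 rose 223-fold and Bpifb1 by a ratio of 288 (79.5 to 2385), with reads shared between members of that family. Fetal and regenerative genes rose in 11 of 13 cases, with Anxa1, an annexin of regenerating epithelium, up 10.8-fold and Il1rn up 9.68-fold (camera adjusted p = 1.79e-11, 0.00127 with estimated correlation). Stem cell genes were mixed, with 8 higher, 2 lower and 3 not called. Tnfrsf19 rose 4.62-fold and Prom1 2.91-fold, while Olfm4, a marker of crypt stem cells, fell by 0.87 (camera adjusted p = 0.00869, 0.189 with estimated correlation). Of 20 cell cycle genes 17 rose, including Mcm2 (1.77-fold) and Rrm2 (1.88-fold), and none fell (camera adjusted p = 6.43e-06, 0.184 with estimated correlation).

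Among differentiated cells, enterocyte and enteroendocrine genes were mostly lower in adenoma, of which only the second list stayed called with an estimated correlation, and the other cell types were mixed. Among enterocyte genes 17 of 21 fell and none rose. Anpep, a brush border peptidase, was 3.21-fold lower, and Vil1, which bundles actin in microvilli, was 1.98-fold lower (camera adjusted p = 2e-08, 0.184 with estimated correlation). Of 15 enteroendocrine genes 11 fell, with Gcg, the glucagon precursor, 3.08-fold lower and Scg2 2.58-fold lower (camera adjusted p = 6.43e-06, 0.0145 with estimated correlation). Of 14 Paneth cell genes 9 fell and 4 rose. Lyz1, the Paneth cell lysozyme, fell by 1.45, Defa24 was 3.53-fold lower and Cd24a rose by 0.97 (camera adjusted p = 0.0183, 0.49 with estimated correlation). The 5 largest falls were the defensins Defa21, Defa22, Defa26 and Defa3, by 3.95-fold to 4.92-fold with reads shared between copies, and the aldo-keto reductase Akr1b7 at 4.67-fold. Among goblet cell genes 2 rose, 5 fell and 4 were not called (camera adjusted p = 0.463), with Zg16 1.91-fold and Tff3 1.68-fold lower. In the tuft cell list Avil, an actin-bundling protein, rose 9.86-fold, while Trpm5, the taste channel, was 1.74-fold lower as 1 of 3 that fell, with 4 not called (camera adjusted p = 0.489).

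Xenobiotic metabolism fell in 17 of 21 genes and rose in 1, and Cyp3a11 fell by 2.10 (camera adjusted p = 1.51e-06, 0.255 with estimated correlation). Distal ileum genes fell in 5 of 7 (camera adjusted p = 0.000292, 0.135 with estimated correlation) and colon genes in 4 of 6 (median -0.66, camera adjusted p = 0.0265, 0.148 with estimated correlation). Without the filter on low counts the colon median turned to 0.117 and the call ended (adjusted p = 0.284). Fabp6, an ileal bile acid carrier, changed by -1.34 ± 0.61 (adjusted p = 0.0739). Of the proximal intestine genes 2 rose, 4 fell and 2 were not called (camera adjusted p = 0.738). Antimicrobial genes rose in 3 and fell in 4 of 14 (camera adjusted p = 0.607). Pla2g2a, a secreted phospholipase known to modify tumour number in Min mice, rose 2.83-fold. Iron and HIF2 targets rose in 2 and fell in 4 of 14 (camera adjusted p = 0.289), BMP genes rose in 4 of 12 with Bmp7 at 2.39-fold and Id1 at 1.72-fold (camera adjusted p = 0.276), and Notch genes rose in 6 and fell in 3 of 12 (camera adjusted p = 0.276). Imprinted genes (4 rose and 2 fell of 15, camera adjusted p = 0.76), DNA methylation enzymes (4 rose of 10, camera adjusted p = 0.11) and p53 targets (5 rose and 3 fell of 16, camera adjusted p = 0.563) were not called as lists.

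In the mean of 4 backgrounds matrix remodelling and inflammation genes were higher in adenoma, and smooth muscle and antigen presentation genes were lower. Of these list calls only the matrix list remained with an estimated correlation. All 14 matrix genes rose, with Plaur, the urokinase receptor, up 7.75-fold and Mmp14 up 4.06-fold (camera adjusted p = 2.71e-09, 0.0145 with estimated correlation). Inflammation genes rose in 9 of 12 and fell in 1, with Lcn2 up 14.2-fold and Ptgs2, the inducible prostaglandin synthase, up 9.52-fold (camera adjusted p = 0.000193, 0.0953 with estimated correlation). All 10 smooth muscle genes fell, with Myh11 at -1.32 ± 0.29 (camera adjusted p = 0.000757, 0.39 with estimated correlation). All 11 MHC class I genes fell (B2m by 1.28, camera adjusted p = 2.73e-07, 0.15 with estimated correlation), as did all 7 MHC class II genes (H2-Aa by 1.35, camera adjusted p = 0.00124, 0.368 with estimated correlation). T cell genes fell in 5 of 13 (camera adjusted p = 0.0151, 0.521 with estimated correlation), and interferon genes fell in 8 of 22 (camera adjusted p = 0.0198, 0.521 with estimated correlation). Mast cell genes rose in 3 of 7 (camera adjusted p = 0.00275, 0.255 with estimated correlation).

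The other cell type lists were not called. They were B and plasma cells (3 fell of 11, camera adjusted p = 0.253), myeloid cells (3 rose and 6 fell of 12, camera adjusted p = 0.536), fibroblasts (4 rose of 12, camera adjusted p = 0.289), endothelium (3 rose and 1 fell of 10, camera adjusted p = 0.191), enteric nerves (1 rose and 4 fell of 8, camera adjusted p = 0.445), pancreas (2 rose of 3, camera adjusted p = 0.178) and fat (2 fell of 9, camera adjusted p = 0.607). Adjusted over the list alone, the counts in adenoma differed from those over all genes in 6 lists. These were goblet cells (4 rose and 5 fell), cell cycle (18 rose), fetal and regenerative genes (12 rose), Notch (6 rose and 4 fell), mast cells (4 rose) and distal ileum (7 fell). Over all 13657 genes 6172 were called, 3238 higher and 2934 lower in adenoma, and 1618 of them by over 2-fold.

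**Figure D1:**
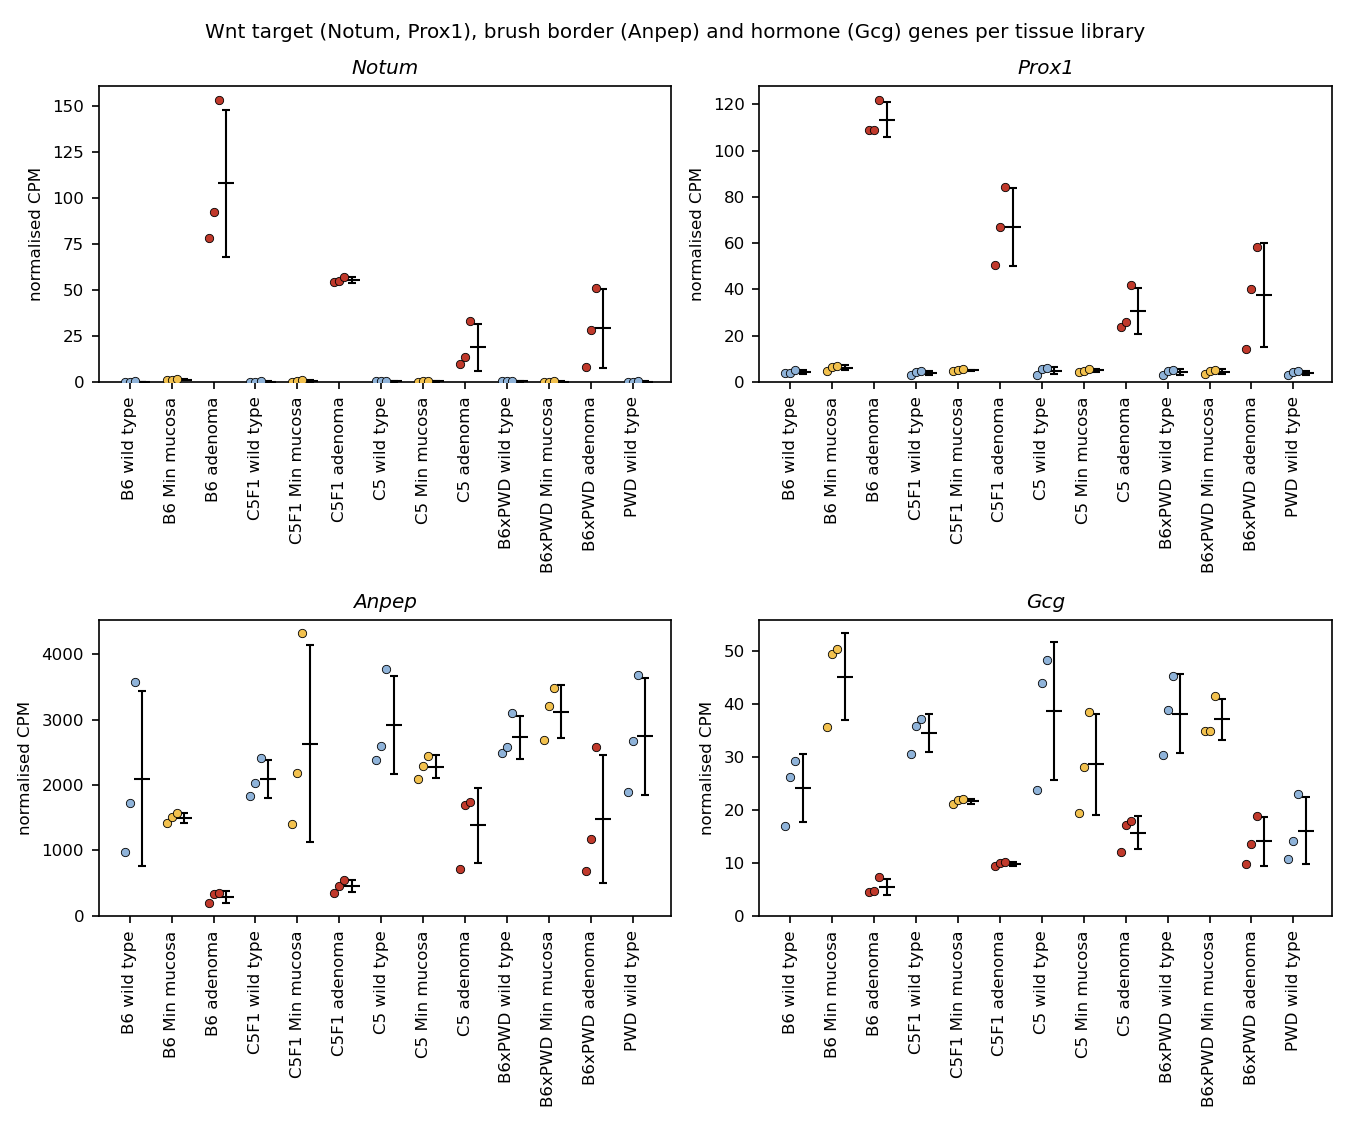
Normalised CPM of named genes in the tissue groups on a linear axis, with 1 point per library and a dash with error bar for the group mean and SD. Notum averaged 108 CPM in B6 adenoma, 55.4 in C5F1, 18.7 in C5 and 29.0 in B6xPWD.

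Within single backgrounds the most genes were called in B6. Gata4, a transcription factor of the proximal small intestine, was at 0 to 0.875 CPM in B6 Min mucosa and 1.07 to 25.4 CPM in B6 adenoma, but at 38.0 to 58.9 and 18.03 to 26.6 CPM in C5F1. The proximal intestine median rose by 0.46 in B6 and fell by 1.72 in C5F1. A difference in the sampled position along the gut therefore stays open as part of these effects. In B6 adenoma Notum reached 108 ± 39.8 CPM (SD, n = 3), against 55.4 ± 1.44 in C5F1, 18.7 ± 12.6 in C5 and 29.0 ± 21.6 in B6xPWD. Prox1 reached 113 ± 7.55 CPM in B6, 67.1 ± 16.9 in C5F1, 30.5 ± 9.87 in C5 and 37.6 ± 22.3 in B6xPWD. Genes called between adenoma and Min mucosa numbered 3647 in B6 (1781 higher, 1866 lower), 2801 in C5F1 (1482 and 1319), 378 in C5 (354 and 24) and 2241 in B6xPWD (1288 and 953). The median absolute change over all genes was 0.44 in B6, 0.40 in C5F1, 0.24 in C5 and 0.38 in B6xPWD. Across genes, which are not independent replicates, the effects correlated at 0.831 ± 0.0384 (jackknife SE, pooled around a common mean over groups) between B6 and C5F1, 0.751 ± 0.0918 between B6 and C5 and 0.593 ± 0.184 between B6 and B6xPWD. The other pairs were C5F1 and C5 (0.786 ± 0.0812), C5F1 and B6xPWD (0.722 ± 0.113) and C5 and B6xPWD (0.643 ± 0.172).

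These counts depended on single libraries. In C5 the count was 207 without adenoma replicate 1, 224, 225 and 192 without Min mucosa replicates 1, 2 and 3, and 733 with the replicate block on adenoma and Min mucosa alone. In C5F1 it was 1788 without adenoma replicate 3. In B6xPWD it was 1359 without adenoma replicate 3, 1382 without Min mucosa replicate 3 and 699 with only the compared groups.

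The test of the difference between backgrounds asks whether the adenoma effect depends on PWD chromosome 5 or on the whole PWD genome. Gcg was lower in adenoma than in Min mucosa by a smaller step in C5 than in B6. It went from 45.2 ± 8.23 to 5.49 ± 1.54 CPM in B6 and from 28.6 ± 9.55 to 15.7 ± 3.10 CPM in C5 (n = 3 each), a difference of 2.20 ± 0.39 (adjusted p = 0.023). Npy2r, a receptor for neuropeptide Y, differed by -4.63 ± 0.83 (adjusted p = 0.023), and Tmtc4, a protein of the endoplasmic reticulum, by -1.40 ± 0.27 (adjusted p = 0.0247). Of the 15 genes called, 10 had a higher adenoma effect in C5 and 5 a lower one. The others were Acacb (2.60 ± 0.52), Gal3st2 (1.97 ± 0.42), Ceacam18 (1.64 ± 0.35), Slc9a2 (1.54 ± 0.30), Tmem236 (1.41 ± 0.28), Slc7a9 (1.29 ± 0.27), Adk (1.19 ± 0.24), Cadps2 (1.12 ± 0.22), Cds1 (0.96 ± 0.19), Habp2 (-2.24 ± 0.44), Nkd1 (-2.51 ± 0.50) and Spp1 (-4.62 ± 0.99), named after their values were seen. The difference was not called for Notum (-0.38, adjusted p = 0.988), Lgr5 (-1.30, adjusted p = 0.123), Prox1 (-1.60, adjusted p = 0.139) or Anpep (1.66, adjusted p = 0.272).

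The 15 calls of the unpaired fit were fragile. The count was 0 without B6 adenoma replicate 2, B6 Min mucosa replicate 1 or 2, C5 adenoma replicate 2 or 3, or C5 Min mucosa replicate 1 or 3. It was 9 without B6 adenoma replicate 1 or B6 Min mucosa replicate 3, 7 without C5 adenoma replicate 1, 5 without B6 adenoma replicate 3 and 2 without C5 Min mucosa replicate 2. At an unadjusted p under 0.05 edgeR gave 1276 genes where 683 are due to chance, and DESeq2 called 133. With the replicate block the count was 81, and 403 with the block on adenoma and Min mucosa alone, 94 with only the compared groups and 7 without the filter on low counts. Gcg was not called without B6 adenoma replicate 1 or 2, B6 Min mucosa replicate 1 or 2, C5 adenoma replicate 2 or 3, or C5 Min mucosa replicate 1 or 3 (adjusted p = 0.0551 to 0.0979). Npy2r was not called without B6 adenoma replicate 2, B6 Min mucosa replicate 1 or 2, C5 adenoma replicate 2 or 3, or any C5 Min mucosa library (adjusted p = 0.0551 to 0.0932). Tmtc4 was called without B6 adenoma replicate 1 but not without any 1 of the other 11 libraries (adjusted p = 0.0601 to 0.102).

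Between B6xPWD and B6 the adenoma effect differed for 86 genes, 65 with a higher and 21 with a lower effect in B6xPWD. Lect2, a secreted chemotaxin, had the smallest p (2.26e-05 adjusted). It had no counts in B6 Min mucosa and 31 to 183 counts in B6 adenoma, but 37 to 107 counts in B6xPWD Min mucosa, so the fitted difference of -8.47 ± 1.0 depends on the prior count. Tmtc4 differed by -1.82 ± 0.27 (adjusted p = 0.00106) and S1pr4, a lymphocyte receptor for sphingosine-1-phosphate, by 6.73 ± 1.09 (adjusted p = 0.00271). Gcg (1.70, adjusted p = 0.036) and Lgr5 (-1.93, adjusted p = 0.0144) were also called. The count was 10 and 14 without B6 adenoma replicates 1 and 2, 50 and 15 without B6 Min mucosa replicates 1 and 3, 17, 403 and 331 without B6xPWD adenoma replicates 1, 2 and 3, and 8, 7 and 13 without B6xPWD Min mucosa replicates 1, 2 and 3. It was 518 with the replicate block on adenoma and Min mucosa alone, 224 with DESeq2 and 6 with only the compared groups, where Tmtc4 was not called (adjusted p = 0.0604). Between C5F1 and B6 no gene was called by edgeR, with 397 at an unadjusted p under 0.05. DESeq2 also called 0, while the replicate block on adenoma and Min mucosa alone gave 41 and only the compared groups 19.

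Min mucosa was compared with wild-type mucosa to ask what the Min allele does outside tumours. A single gene passed the test. P4ha1, a collagen prolyl hydroxylase on chromosome 10, was higher in Min mucosa by 0.85 ± 0.15 (n = 12 and 12, adjusted p = 0.0266), named after its value was seen. Retnlb, a goblet cell protein, averaged 18.02 ± 27.6 CPM in Min mucosa and 12.2 ± 22.2 CPM in wild type (1.92 ± 0.57, adjusted p = 0.304). Dmbt1 (0.62 ± 0.28, adjusted p = 0.616), the Wnt genes Wif1 (1.90 ± 0.69, adjusted p = 0.498) and Dkk2 (0.73 ± 0.29, adjusted p = 0.543), Apc (0.17 ± 0.09, adjusted p = 0.712) and Pla2g2a (0.09 ± 0.17, adjusted p = 0.954) were not called. The enterocyte genes Vil1 (-0.17) and Krt20 (-0.19), the Paneth genes Itln1 (-0.37) and Defa24 (-0.29), Atoh1 of the secretory lineage (-0.24), the cell cycle genes Mcm5 (-0.18) and Foxm1 (-0.26), Ccl2 (1.34 ± 0.68), Nos2 (0.35), the interferon genes Xaf1 (-0.47) and Oas1a (-0.45), and the hypoxia targets Ankrd37 (0.52) and Egln3 (0.39) lay between adjusted p = 0.613 and 0.849.

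Stromal lists moved in Min mucosa although no member was called over all genes. In the matrix list Mmp13 was at 0.94 ± 0.24 (adjusted p = 0.204), and 6 of 14 genes rose over the list alone (camera adjusted p = 7.97e-06, 0.125 with estimated correlation). Of 10 endothelial genes 6 rose over the list alone, with the VEGF receptor Kdr at 0.82 ± 0.18 (camera adjusted p = 8.24e-07, 0.0943 with estimated correlation). Of 12 fibroblast genes 2 rose on that basis, with Pdgfra at 0.48 (camera adjusted p = 7.97e-06, 0.186 with estimated correlation). Fat genes were lower, 5 of 9 over the list alone, with the adipokine Adipoq at -4.90 ± 1.10 and Cfd at -4.44 ± 0.98 (camera adjusted p = 3.17e-08, 0.0943 with estimated correlation). The myeloid list was called higher (camera adjusted p = 0.0222, 0.648 with estimated correlation) and the interferon list lower (camera adjusted p = 0.0257, 0.799 with estimated correlation), with no member of either called over the list alone. Goblet, fetal and regenerative, Notch and antimicrobial genes had 1 each that rose on that basis.

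The single call in Min mucosa rested on individual libraries. The count was 0 without B6 Min mucosa replicate 2, B6 wild-type replicate 1 or 2, B6xPWD Min mucosa replicate 1 or 2, B6xPWD wild-type replicate 1 or 2, C5 Min mucosa replicate 2 or 3, C5 wild-type replicate 1 or 3, C5F1 Min mucosa replicate 2 or 3, or C5F1 wild-type replicate 1. It was 2 without C5F1 Min mucosa replicate 1, 3 without B6 Min mucosa replicate 1, B6xPWD Min mucosa replicate 3 or B6xPWD wild-type replicate 3, 6 without C5F1 wild-type replicate 3 and 8 without C5 wild-type replicate 2. At an unadjusted p under 0.05 there were 1014 genes, and DESeq2 called 13. In B6 alone 71 genes were called, 34 higher and 37 lower. The 2 B6 groups differ in markers of gut position, with Gata4 at 0.337 ± 0.470 CPM in Min mucosa and 47.9 ± 41.0 in wild type and Fabp6 at 2166 ± 575 and 640 ± 842 CPM, so position stays open as a cause beside the Min allele. The count of 71 was 14 without the 3 libraries low in Fabp6, 0 without B6 Min mucosa replicate 1 or B6 wild-type replicate 2, 15 without Min mucosa replicate 2 or wild-type replicate 3, 201 without wild-type replicate 1, 0 with only the compared groups and 178 with DESeq2. In C5F1, C5 and B6xPWD edgeR called 0 genes, with 690, 993 and 488 at an unadjusted p under 0.05, and DESeq2 called 1 in each. The C5 count was 3 without wild-type replicate 2, and the C5F1 count was 86 with only the compared groups.

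PWD and B6 wild-type mucosa were compared to describe the donor strain. Alignment of PWD alleles to the C57BL/6 reference was not tested on reads, so lower counts in PWD and B6xPWD, above all in polymorphic families, stay open to it. Pla2g2a averaged 1509 ± 435 CPM in PWD and 25.2 ± 7.31 CPM in B6 (SD, n = 3 each), a rise of 58.6-fold (5.87 ± 0.41, adjusted p = 2.62e-12). Retnlb rose 133-fold. Some antigen presentation and interferon genes were lower in PWD, 2 of 7 in MHC class II, 4 of 11 in MHC class I with 1 higher, and 7 of 22 interferon genes with 1 higher. MHC class I was not called as a list, and the other 2 list calls ended with an estimated correlation. H2-Eb1, an MHC class II chain, was at 11.2 ± 1.78 CPM against 359 ± 110 CPM, 31.8-fold lower. Nos2, the inducible nitric oxide synthase, was lower by a ratio of 211 (95% counting interval 71.7 to 1023). Apc was at 145 ± 2.25 CPM against 146 ± 15.2 CPM (-0.01 ± 0.19, adjusted p = 0.99).

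The largest rises in PWD were Mmrn1, a platelet gene also read in C5 (at least 174-fold), Gsta2, a glutathione transferase (at least 62.8-fold), Cel, the bile salt lipase (at least 39.2-fold), Eno1b (at least 25.5-fold) and Slc22a13b-ps (180-fold). The largest falls were Saa1, serum amyloid A (at least 220-fold), Naip6, an inflammasome sensor (at least 87.1-fold), Ocm, a calcium-binding protein on chromosome 5 (at least 76.3-fold), Gsdmc4, a gasdermin (at least 55.8-fold) and Defa3 (ratio 809, 145 to 32011, reads shared with copies). Saa1 was not called without B6 replicate 1 (adjusted p = 0.25) or without PWD replicate 1 (0.068), 2 (0.103) or 3 (0.0565).

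Xenobiotic genes rose in 15 of 21 and fell in 1, with Gsta4 up 20.2-fold and Ugt2b5 up 33.5-fold (16 rose and 2 fell over the list alone, camera adjusted p = 4.1e-07, 0.601 with estimated correlation). Enterocyte genes rose in 9 of 21 (10 over the list alone, camera adjusted p = 9.15e-05, 0.601 with estimated correlation), with the disaccharidases Treh up 5.57-fold and Sis up 4.51-fold. Proximal intestine genes rose in 4 of 8 (5 over the list alone, camera adjusted p = 0.0288, 0.601 with estimated correlation) and fibroblast genes in 3 of 12 (4, camera adjusted p = 0.0167, 0.601 with estimated correlation). Paneth cell genes fell in 10 of 14 and rose in 1 (11 and 1 over the list alone, camera adjusted p = 3.86e-07, 0.601 with estimated correlation), with Defa17 at -8.55. Cell cycle genes fell in 5 of 20 (6, camera adjusted p = 0.0123, 0.601 with estimated correlation), and antimicrobial genes fell in 6 and rose in 2 of 14 (10 and 2, camera adjusted p = 0.0123, 0.601 with estimated correlation). MHC class II genes fell in 2 of 7 (4 over the list alone, camera adjusted p = 0.0044, 0.601 with estimated correlation), H2-DMb1 by 1.87. Inflammation genes fell in 2 of 12 (3, camera adjusted p = 0.0274, 0.601 with estimated correlation).

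Interferon genes fell in 7 of 22 and rose in 1 (8 and 2 over the list alone, camera adjusted p = 0.0446, 0.724 with estimated correlation). Cxcl10, an interferon-induced chemokine, was lower by a ratio of 25.1 (8.29 to 125). B and plasma cell genes fell in 5 of 11 (9 over the list alone, camera adjusted p = 0.0258, 0.636 with estimated correlation). MHC class I genes fell in 4 and rose in 1 of 11 (5 and 1, camera adjusted p = 0.0893), with H2-K1 3.42-fold lower and H2-T3 up 3.26-fold. The lists of Wnt targets (2 rose and 3 fell of 24, camera adjusted p = 0.802, Ccnd1 3.07-fold lower and Apcdd1 up 4.86-fold), goblet cells (1 rose and 2 fell of 11, camera adjusted p = 0.406, Spink4 2.96-fold lower), matrix remodelling (4 rose and 1 fell of 14, 5 and 1 over the list alone, camera adjusted p = 0.0893) and endothelium (3 rose of 10, 4 over the list alone, camera adjusted p = 0.343) were not called.

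In total 2560 genes were called between PWD and B6 wild type, 1360 higher and 1200 lower. Fabp6, high in ileum, was at 1.02, 0.144 and 4744 CPM in PWD replicates 1, 2 and 3. In those of B6 it was at 1602, 281 and 36.9 CPM. Gata4 was at 79.7, 132 and 25.2 CPM in PWD and at 1.21, 64.1 and 78.3 CPM in B6. Gut position thus stays open as a cause. Leaving out the 3 under 100 CPM of Fabp6 sets 1 PWD library against 2 of B6. Calls then ended for genes whose log2 change stayed as large or grew, H2-DMb1 (-2.73 after -1.87), Saa1 (-11.8 after -11.3) and Gsdmc4 (-9.60 after -9.34). They also ended for genes whose change shrank, Apcdd1 (1.75 after 2.28), Cxcl10 (-3.26 after -4.30), Sis (1.56 after 2.17), Slc22a13b-ps (3.20 after 7.49), Spink4 (-1.30 after -1.57) and Treh (1.55 after 2.48). With so few libraries these losses do not decide whether the calls depend on position. The count was 1648 without B6 replicate 1, 1540 without PWD replicate 2 and 1034 with only the compared groups, where Sis (0.0644) and Treh (0.094) were not called. H2-DMb1 was also not called without B6 replicate 1 (0.0573) or 2 (0.0834) or without PWD replicate 1 (0.0561), 2 (0.0587) or 3 (0.0877).

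C5 and B6 were compared over wild-type mucosa, Min mucosa and adenoma to look for effects of the donor chromosome 5. The labels do not give the substrain of B6, so differences between B6 and the C5 host outside that chromosome stay open. Genes of that chromosome were called more often than others, in both directions. Hpd, an enzyme of tyrosine breakdown, was lower in C5 by a pooled ratio of 225 (95% counting interval 61.9 to 1859), at 0.0799 ± 0.177 CPM against 8.47 ± 3.31 CPM (n = 9 each, in part paired). Coq5, an enzyme of ubiquinone synthesis, rose 3.02-fold, from 7.95 ± 0.932 to 23.8 ± 3.70 CPM, and Tlr6, a receptor for bacterial lipopeptides, rose 14.9-fold. Rundc3b was 3.80-fold, Ocm 44.1-fold and Zan 7.06-fold lower, and 1700023E05Rik rose 94.3-fold. Rplp0 was 3.57-fold lower, and Ugt2b36 and Ugt2b5 rose 7.97-fold and 6.64-fold, all with reads shared between copies. Outside chromosome 5, Mmrn1 on chromosome 6, without counts in B6, was at least 469-fold higher in C5, Bglap3 on chromosome 3 rose 88.4-fold to 107 ± 32.6 CPM, and Lcn2 was 3.77-fold lower. Apc did not differ (0.01 ± 0.11, adjusted p = 0.979). Pla2g2a was at 27.2 ± 11.9 CPM against 76.7 ± 73.5 CPM, 2.05-fold lower in C5 (adjusted p = 0.000631).

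**Figure D2:**
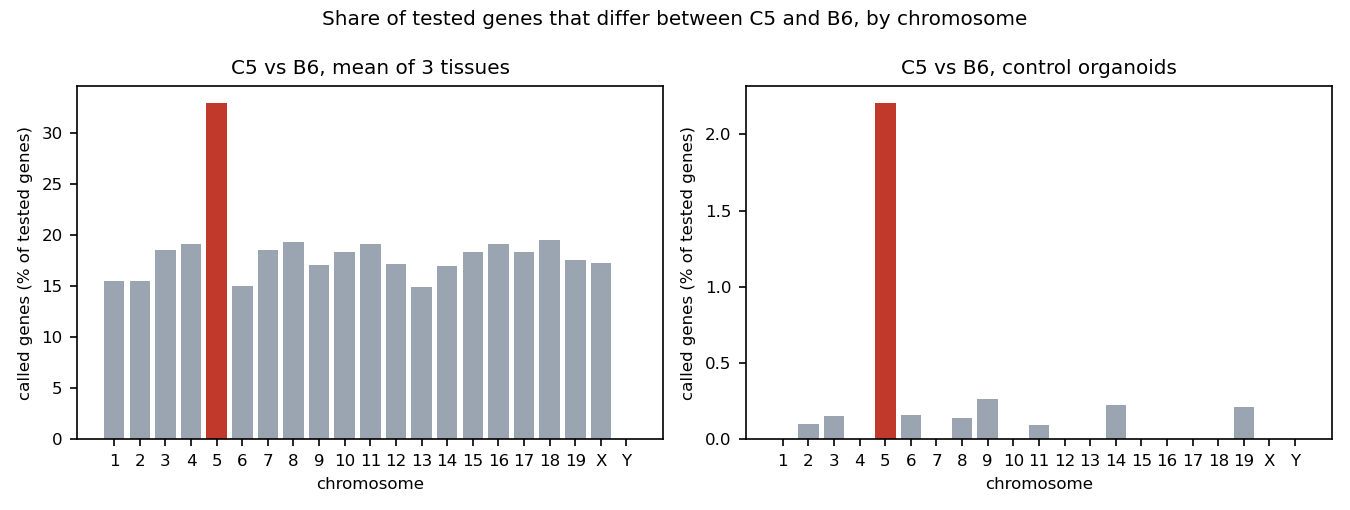
Percent of the tested genes of each chromosome that were called between C5 and B6, over 3 tissues and in control organoids, with chromosome 5 in red. On chromosome 5 33.0% were called over 3 tissues and 2.21% in organoids, against 17.7% and 0.0722% on the other chromosomes.

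Over the 3 tissues, with pairs ignored and chance not excluded (below), 2542 genes were called, 1400 higher and 1142 lower in C5, and 447 by over 2-fold. Chromosome 5 held 286 of the 2535 with a position, or 11.3% against 6.37% of the genes tested (Fisher's exact odds ratio 2.30, p = 9.3e-26), 149 higher and 137 lower. Without 1 library this share was 10.2 to 13.99%. In wild-type mucosa 201 genes were called, 136 higher and 65 lower, and 72 (35.8%) were on chromosome 5 (Fisher's exact odds ratio 8.85, p = 1.06e-35). That count was 93, 32 and 728 without B6 replicates 1, 2 and 3, 132, 57 and 75 without those of C5, 753 without the 3 libraries low in Fabp6, 785 without those over 60% Rn45s, 332 with DESeq2 and 9 with only the compared groups.

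Several epithelial lists were higher in C5 over the 3 tissues, but not in each tissue. Gata4 was at 0 to 0.875 CPM in B6 and 2.20 to 74.0 CPM in C5 Min mucosa, and Fabp6 at 390 ± 71.4 and 1213 ± 95.5 CPM in adenoma, so gut position stays open as a cause here and in adenoma. The enterocyte median was -0.33 in wild-type mucosa, with no member called by edgeR, and 1.47 in adenoma, and the Paneth median was -0.50 and 1.13. The xenobiotic median was 1.12 in wild-type mucosa, with 2 called, and 1.64 in adenoma. Xenobiotic genes rose in 10 of 21 (12 over the list alone, camera adjusted p = 1.79e-07, 0.535 with estimated correlation), with Cyp3a25 up 3.52-fold. Enterocyte genes rose in 11 of 21, with the intestinal phosphatase Alpi up 2.53-fold and Anpep up 2.17-fold (camera adjusted p = 0.000267, 0.535 with estimated correlation). Distal ileum genes rose in 2 of 7 (camera adjusted p = 0.024, 0.535 with estimated correlation), Wnt targets fell in 5 and rose in 1 of 24, with Ephb3 1.46-fold lower and Fzd7 up 1.41-fold (camera adjusted p = 0.0052, 0.535 with estimated correlation), and mast cell genes fell in 2 of 7 (camera adjusted p = 0.00376, 0.535 with estimated correlation). Cell cycle genes fell in 5 and rose in 1 of 20 (6 and 1 over the list alone, camera adjusted p = 0.024, 0.651 with estimated correlation). Enteroendocrine genes rose in 6 of 15 (7 over the list alone, camera adjusted p = 0.128), tuft cell genes in 3 of 8 (5, camera adjusted p = 0.114), MHC class I genes in 3 of 11 (camera adjusted p = 0.128), Paneth genes in 4 of 14 with 1 lower (camera adjusted p = 0.554) and interferon genes in 4 of 22 with 1 lower (camera adjusted p = 0.128).

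Among single members Reg3a rose 2.85-fold, Ang4 2.49-fold, Fcgbp 2.00-fold, Zg16 1.74-fold, H2-T3 2.13-fold, Ifih1 1.97-fold, Ddx58 1.56-fold and H2-T23 1.33-fold. H2-T23 was not called without B6 replicate 1 of adenoma (adjusted p = 0.0783), Min mucosa (0.0538) or wild type (0.0763), or without C5 wild-type replicate 1 (0.0521). No MHC class II gene was called by edgeR (camera adjusted p = 0.647), with Ciita at 0.44 (adjusted p = 0.425) and H2-Aa at 0.43 (adjusted p = 0.452).

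The 2 crosses carry 1 copy of the PWD chromosome 5, and C5 and PWD carry 2. Coq5, chosen for its small p between C5 and B6, averaged in wild-type mucosa 8.29 ± 1.11 CPM in B6, 16.0 ± 3.63 in C5F1, 25.9 ± 5.42 in C5, 18.3 ± 3.12 in B6xPWD and 31.0 ± 5.04 in PWD (n = 3 each). Hpd, chosen likewise, averaged 7.65 ± 0.764, 4.85 ± 1.16, 0.173 ± 0.299 and 4.05 ± 0.788 CPM in the first 4 of these and had no counts in PWD. For 216 chromosome 5 genes called between C5 and B6 in adenoma, the median wild-type change in the same direction was 0.19 ± 0.09 in C5F1 (jackknife SE), 0.29 ± 0.20 in C5, 0.28 ± 0.16 in B6xPWD and 0.46 ± 0.15 in PWD. The step from C5F1 to C5 lies within these SE, and all 4 values share the B6 libraries, so the set does not show dosage. In the same order 147, 150, 151 and 159 of them went the same way, or 68.1, 69.4, 69.9 and 73.6%. For 2204 called genes of other chromosomes the medians were 0.08, 0.03, 0.20 and 0.09, with 59.4, 53.4, 64.8 and 55.4% going the same way.

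In C5F1 wild-type mucosa 3 genes were called against B6, all higher. Named after their values were seen, they were Hgfac (1.94 ± 0.34, adjusted p = 0.00941), 1700023E05Rik (5.43 ± 0.80, adjusted p = 0.000667) and Mmrn1, without counts in B6. The count was 53 and 195 without B6 replicates 1 and 3, 6 without C5F1 replicate 2, 182 without the 3 libraries low in Fabp6, 215 without those over 60% Rn45s, 118 with DESeq2 and 1 with only the compared groups. In B6xPWD wild-type mucosa 1311 genes were called, 723 higher and 588 lower, and Pla2g2a averaged 928 ± 223 CPM. That count was 704 and 597 without B6 replicates 1 and 2, 701 without B6xPWD replicate 2 and 351 with only the compared groups.

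C5 and B6 adenomas were compared to ask how tumours differ with the donor chromosome. Of 24 Wnt targets 14 were lower and 1 higher in C5 adenoma, and 13 of 21 enterocyte genes were higher. Both list calls ended with an estimated correlation (adjusted p = 0.0925 and 0.25). Prox1 was at 30.5 ± 9.87 CPM in C5 and 113 ± 7.55 CPM in B6 (n = 3 each), 3.69-fold lower (-1.88 ± 0.29, adjusted p = 4.03e-05). Notum fell by 2.50, Nkd1 by 2.08 and Wif1 by 2.73, and Anpep rose 4.79-fold, from 289 ± 86.5 to 1383 ± 575 CPM. Nptx2, a secreted pentraxin on chromosome 5, was at 4.97 ± 1.63 CPM against 151 ± 36.8 CPM, 30.8-fold lower. Alb, serum albumin on chromosome 5, was 40.3-fold lower and Hpd at least 35.99-fold lower. Pla2g2a was 4.19-fold lower, at 40.8 ± 10.4 CPM against 171 ± 36.9 CPM.

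Among the largest rises in C5 adenoma were Mmrn1 (at least 166-fold), Bglap3 (112-fold), Slc5a12, a lactate transporter (16.9-fold), Ugt2a3 (15.6-fold) and Scarna3a (4.25 ± 1.52). On chromosome 5, Sult1b1, a sulfotransferase, rose 5.48-fold, Rplp0 was 4.16-fold lower and 1700023E05Rik rose 102-fold. Scarna3a was not called without B6 adenoma replicate 1, 2 or 3 (adjusted p = 0.0999, 0.144 and 0.119) or C5 adenoma replicate 1 (0.798). Ugt2a3 was not called without B6 adenoma replicate 1, 2 or 3 (adjusted p = 0.0573, 0.112 and 0.104) or C5 adenoma replicate 1 or 3 (0.0549 and 0.118). The mast cell proteases Mcpt1 (94.3-fold) and Mcpt2 (38.8-fold) were lower, with reads shared between them, and Mcpt2 was not called without B6 adenoma replicate 3 (adjusted p = 0.0584).

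Wnt targets fell in 14 and rose in 1 of 24 (16 and 1 over the list alone, camera adjusted p = 1.79e-10, 0.0925 with estimated correlation), with Ephb3, a crypt receptor, 2.62-fold lower. Enterocyte genes rose in 13 of 21 (15 over the list alone, camera adjusted p = 8.28e-08, 0.25 with estimated correlation), with Vil1 up 2.76-fold. Xenobiotic genes rose in 9 of 21 (11 over the list alone, camera adjusted p = 1.82e-07, 0.265 with estimated correlation), with Ugt2b34 up 2.97-fold and Ugt2b5 up 12.9-fold. Enteroendocrine genes rose in 6 of 15, with Gcg at 1.55 and Chgb at 2.18 (camera adjusted p = 0.000433, 0.146 with estimated correlation). Distal ileum genes rose in 3 of 7 (camera adjusted p = 0.000362, 0.18 with estimated correlation) and colon genes in 2 of 6 (3 over the list alone, camera adjusted p = 0.0344, 0.183 with estimated correlation). Cell cycle genes fell in 5 of 20 (6 over the list alone, camera adjusted p = 0.00216, 0.409 with estimated correlation). Fetal and regenerative genes fell in 3 of 13 (camera adjusted p = 0.00977, 0.25 with estimated correlation), with Clu at -2.08, and matrix genes in 5 of 14 (camera adjusted p = 0.00674, 0.309 with estimated correlation), with Mmp14 at -1.69. Paneth genes rose in 6 and fell in 3 of 14 (camera adjusted p = 0.0921), with Ang4 up 5.04-fold and Gm15284 3.69-fold.

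Immune lists also moved with the adenoma background. MHC class I genes rose in 4 of 11 (5 over the list alone, camera adjusted p = 7.1e-05, 0.285 with estimated correlation), with B2m up 2.87-fold and H2-T3 up 4.40-fold. Interferon genes rose in 6 of 22 (8 over the list alone, camera adjusted p = 0.00325, 0.447 with estimated correlation), with Ifih1 up 3.30-fold and Ifit1 up 4.63-fold. Ifit1 was not called without B6 adenoma replicate 1 (adjusted p = 0.0794) or C5 adenoma replicate 1 (0.0516). T cell genes rose in 4 of 13 (6 over the list alone, camera adjusted p = 0.00485, 0.464 with estimated correlation), with Cd8a at 2.15. Mast cell genes fell in 6 of 7 (camera adjusted p = 7.94e-05, 0.18 with estimated correlation). No MHC class II gene was called by edgeR (camera adjusted p = 0.0155, 0.479 with estimated correlation), with H2-Aa at 1.68 (adjusted p = 0.0744) and H2-Ab1 at 1.48 (0.0964), but both were called with only the compared groups (0.0015 and 0.00499). Fibroblast genes fell in 2 of 12 (3 over the list alone, camera adjusted p = 0.0491, 0.479 with estimated correlation), BMP genes fell in 3 and rose in 1 of 12 (camera adjusted p = 0.0491, 0.409 with estimated correlation) and pancreas genes fell in 2 of 3 (camera adjusted p = 0.0344, 0.18 with estimated correlation). Goblet cell genes rose in 2 of 11 (3 over the list alone, camera adjusted p = 0.192), Fcgbp by 2.73-fold and Zg16 by 2.72-fold, and antimicrobial genes rose in 2 and fell in 1 of 14 (3 and 1, camera adjusted p = 0.192), with Reg3a up 5.59-fold. Smooth muscle genes rose in 2 of 10 (camera adjusted p = 0.133), enteric nerve genes in 3 of 8 (camera adjusted p = 0.363) and tuft cell genes in 3 of 8 (3 and 1 lower over the list alone, camera adjusted p = 0.219).

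Between C5 and B6 adenoma 2427 genes were called, 1296 higher and 1131 lower, and 1273 by over 2-fold, while Apc was not (0.12 ± 0.18, adjusted p = 0.704). Chromosome 5 held 216 of the 2420 with a position, or 8.93% (Fisher's exact odds ratio 1.59, p = 3.21e-08). The count was 1370 without B6 adenoma replicate 2 and 1265 without C5 adenoma replicate 3. Between C5F1 and B6 adenoma 66 genes were called, 38 higher and 28 lower. That count was 20 and 9 without B6 adenoma replicates 1 and 2, 10, 29 and 37 without C5F1 adenoma replicates 1, 2 and 3, 222 with DESeq2, 101 with the replicate block and 734 with only the compared groups. Between B6xPWD and B6 adenoma 2312 genes were called, 1359 higher and 953 lower, and Pla2g2a reached 1847 ± 975.3 CPM. That count was 1526 and 1338 without B6 adenoma replicates 1 and 2 and 804 with only the compared groups.

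AZA-treated and control organoids were compared to ask which genes respond to a drug that lowers DNA methylation. Interferon response genes (20 of 21), germline genes (8 of 12) and enterocyte genes (21 of 21) rose, and cell cycle genes fell (19 of 20). These list calls ended with an estimated correlation (adjusted p = 0.147 to 0.167). Ifit1, an interferon-induced antiviral gene, rose 49.9-fold, from 4.17 ± 2.21 to 216 ± 158 CPM (SD, n = 4 each, 5.64 ± 0.48, adjusted p = 6.95e-07). Lyz1 rose 9.99-fold, and Lgr5, the crypt stem cell receptor, was 5.87-fold lower at 28.5 ± 12.6 CPM against 157 ± 23.2 CPM. Pet2 on the X chromosome rose at least 415-fold, AI662270 by a ratio of 1921 (344 to 75917), Pnma5 643-fold, Oas3, an antiviral synthetase, at least 156-fold and Cdh19, a cadherin, 491-fold. The largest falls were Hist1h4j (30.4-fold, reads shared with copies), Nhs (26.0-fold), Lipg, endothelial lipase (10.7-fold), Zfp940 (10.4-fold) and Ppef1 (9.73-fold). Zfp940 was not called without B6 control replicate 1 (adjusted p = 0.058).

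Interferon genes rose in 20 of 21 (21 over the list alone, camera adjusted p = 2.67e-14, 0.167 with estimated correlation), with the RNA sensor Ddx58 up 6.32-fold. All 11 MHC class I genes rose (camera adjusted p = 9.61e-10, 0.0997 with estimated correlation). Germline genes rose in 8 of 12 (9 over the list alone, camera adjusted p = 0.000948, 0.147 with estimated correlation), with Asz1 up 43.0-fold and Tex19.1 by a ratio of 419 (74.8 to 16613). Imprinted genes rose in 5 of 11 (camera adjusted p = 0.178), with Igf2 up 6.14-fold and Impact up 2.02-fold. Impact was not called without B6 AZA replicate 1 (adjusted p = 0.0781), B6 control replicate 1 (0.0798), C5 AZA replicate 4 (0.0766) or C5 control replicate 3 (0.0516). DNA methylation enzymes fell in 4 of 10, with Dnmt1 2.12-fold and the helicase Hells 2.37-fold lower (camera adjusted p = 0.0335, 0.239 with estimated correlation). The p53 targets rose in 12 of 16, with Trp53inp1 up 5.09-fold, Ccng1 up 3.01-fold and Cdkn1a, the cell cycle inhibitor, at 2.01 ± 0.20 (camera adjusted p = 1.49e-08, 0.0997 with estimated correlation).

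Cell cycle genes fell in 19 of 20 (20 over the list alone, camera adjusted p = 7.32e-14, 0.147 with estimated correlation), with Top2a 2.73-fold and Ccna2 2.64-fold lower. Stem cell genes fell in 6 and rose in 1 of 14 (6 and 2 over the list alone, camera adjusted p = 0.0278, 0.282 with estimated correlation), with Smoc2 3.26-fold lower. All 21 enterocyte genes rose, with Anpep up 7.28-fold and Apob, the apolipoprotein of chylomicrons, up 3.59-fold (camera adjusted p = 1.92e-20, 0.147 with estimated correlation). Paneth genes rose in 10 of 13 (11 over the list alone, camera adjusted p = 7.8e-07, 0.246 with estimated correlation), with Ang4 up 10.4-fold. Goblet genes rose in 7 of 10 (8 over the list alone, camera adjusted p = 0.00149, 0.147 with estimated correlation), with Tff3 up 1.75-fold and Spink4 up 1.71-fold. Enteroendocrine genes rose in 9 and fell in 1 of 16 (11 and 1 over the list alone, camera adjusted p = 1.14e-05, 0.147 with estimated correlation). Xenobiotic genes rose in 19 of 21 (19 and 1 lower over the list alone, camera adjusted p = 2.67e-14, 0.0997 with estimated correlation), with Cyp3a11 up 15.8-fold and Cyp3a25 up 7.57-fold. Antimicrobial genes rose in 9 and fell in 1 of 13 (camera adjusted p = 1.09e-05, 0.0997 with estimated correlation), and Pla2g2a, without counts in control organoids, rose at least 47.0-fold.

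Fetal and regenerative genes rose in 7 of 11, with Clu up 249-fold and S100a6 up 9.19-fold (camera adjusted p = 2.45e-05, 0.204 with estimated correlation). Inflammation genes rose in 3 of 6 (camera adjusted p = 0.00379, 0.211 with estimated correlation), distal ileum genes in 5 of 6 (camera adjusted p = 0.000599, 0.189 with estimated correlation) and fibroblast genes in 3 of 5 (camera adjusted p = 0.0464, 0.21 with estimated correlation). Wnt targets rose in 5 and fell in 4 of 21 (8 and 4 over the list alone, camera adjusted p = 0.614), matrix genes rose in 3 and fell in 1 of 7 (4 and 1, camera adjusted p = 0.165), MHC class II genes rose in 3 of 5 (camera adjusted p = 0.0613) and no tuft cell gene was called by edgeR (camera adjusted p = 0.486). Over 13395 genes 3818 were called, 2005 higher and 1813 lower, and 1810 by over 2-fold.

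**Figure D3:**
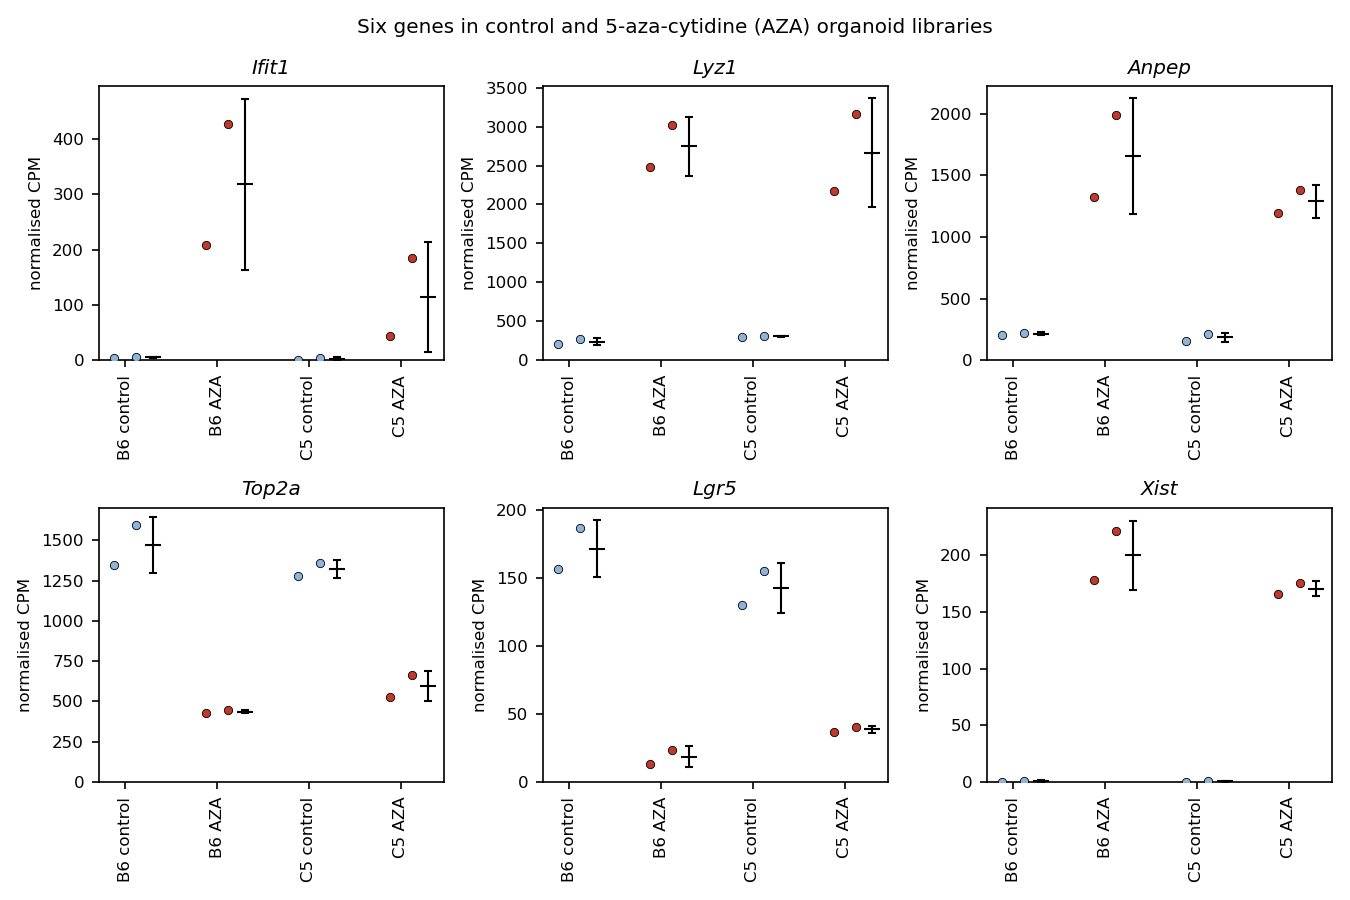
Normalised CPM of named genes in control and AZA-treated organoids of B6 and C5, with 1 point per library and a dash with error bar for the group mean and SD. Lgr5 averaged 172 CPM in B6 control and 18.4 CPM in B6 AZA organoids, and 143 and 38.6 CPM in C5.

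By background AZA changed 2157 genes in B6 (1232 higher, 925 lower) and 1949 in C5 (1080 and 869). The effects correlated at 0.564 across genes. The B6 count was 1149 and 1274 without control replicates 1 and 2, and the C5 count was 1232 without control replicate 4 and 951 with only the compared groups. No gene was called by edgeR for a difference of the AZA effect between C5 and B6, with 609 at an unadjusted p under 0.05 where 670 are due to chance, and DESeq2 also called 0. The count was 2 without B6 control replicate 1, 26 and 7 without C5 AZA replicates 3 and 4, 23 and 6 without C5 control replicates 3 and 4, 34 without the filter on low counts and 21 with the replicate block.

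C5 and B6 control organoids were compared to find effects of the donor chromosome in epithelium alone. Most called genes lay on chromosome 5. Prom1, a pentaspan membrane protein of stem cells, was at 156 ± 7.70 CPM in C5 and 598 ± 20.9 CPM in B6 (n = 2 each), 3.84-fold lower (-1.94 ± 0.17, adjusted p = 2.54e-05). Pkd2, the polycystin channel, was at least 76.4-fold lower, and the metalloreductases Steap1 and Steap2 were 43.5-fold and 38.4-fold lower. Cacna2d1, a calcium channel subunit, rose 9.46-fold, Arpc1b, an actin nucleation subunit, 4.60-fold, 1700023E05Rik 135-fold, Atp10d by a ratio of 66.2 (18.001 to 552), and Ugt2b36, Ugt2b5 and Rpl21 by 6.92-fold, 3.87-fold and 25.1-fold with reads shared between copies. Outside chromosome 5, Bglap3 rose by a ratio of 231 (63.7 to 1916), Olfm4 rose 5.93-fold and Ube2l6, a conjugating enzyme for ISG15, was 6.65-fold lower. Pla2g2a had no counts in either group.

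Of the 28 genes called, 17 higher and 11 lower, 19 (67.9%) were on chromosome 5 (Fisher's exact odds ratio 31.2, p = 8.06e-17). Of these, 16 were also called over the 3 tissues, all 16 in the same direction, where 6.45 are due to chance. The count of 28 was 139 and 45 without C5 control replicates 3 and 4 and 116 without the filter on low counts, and the share on chromosome 5 was 27.5% without C5 control replicate 3. Atp10d was not called without B6 control replicate 1 (adjusted p = 0.211) or C5 control replicate 4 (0.0687) or with only the compared groups (0.121), Olfm4 without B6 control replicate 2 (0.133) or with DESeq2 (0.17), Ube2l6 without C5 control replicate 4 (0.117) or with only the compared groups (0.434), and Ugt2b5 without B6 control replicate 2 (0.0798).

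Among the lists, 1 stem cell gene rose and 1 fell of 14, and 1 of 21 xenobiotic genes rose (4 rose and 1 fell over the list alone). Iron and HIF2 targets were lower as a list (camera adjusted p = 0.0367, 0.949 with estimated correlation), with 1 of 14 lower over the list alone. Every other list was at a camera adjusted p of 0.236 or more. Named members below the threshold were Aldh1a1 (0.78 ± 0.25, adjusted p = 0.594), Gm15284 (1.85 ± 0.54, adjusted p = 0.498), Slc15a1 (1.10), Ang4 (0.86), Agr2 (0.48), Muc2 (0.52), Mcm6 (0.44), Mcm3 (0.43) and Bambi (1.85), and Apcdd1 had no counts in C5 (at least 8.57-fold lower, adjusted p = 0.626). Aldh1a1 was called without C5 control replicate 4 (adjusted p = 0.0125), and Gm15284 (adjusted p = 0.00293) without C5 control replicate 3. Without the filter on low counts Aldh1a1 (adjusted p = 0.00812), Gm15284 (2.39e-18) and Slc15a1 (0.0315) were called, and with only the compared groups Gm15284 was (0.0466).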

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

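The Y-linked gene test in the Xist paragraph, the test of changes relative to Min mucosa, the spreads over libraries beside it, and the splits that part every pair or move pairs together were chosen only after the result was seen; the other tests of this part were planned. A test of the difference between backgrounds singled out the following results. The adenoma effect differed between C5 and B6 for 15 genes, led by Gcg (2.20 on the log2 scale), Npy2r (-4.63) and Tmtc4 (-1.40). It differed between B6xPWD and B6 for 86 genes, among them Lect2 (-8.47, with no counts in B6 Min mucosa), Tmtc4 (-1.82), S1pr4 (6.73) and Gcg (1.70).

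The adenoma effect was smaller in C5 than in B6. More normal mucosa in C5 adenomas is a technical explanation, and a single share of it would shrink rising and falling genes alike. For 100 rising genes the C5 change in CPM was 0.301 of the B6 change (95% bootstrap interval 0.243 to 0.359), and for 100 falling genes it was 0.791 (0.690 to 1.02). The difference of -0.49 (-0.729 to -0.368) is over genes, and its jackknife SE over the 12 libraries was 0.225. It was planned as evidence against normal tissue, but changes in CPM start from unlike levels: Min mucosa of C5 was at a median of 0.574 times that of B6 for 64 rising genes with counts in both, and 1.38 times for the falling genes. Relative to the Min mucosa of each background the ratios were 0.514 ± 0.179 for these 64 and 0.598 ± 0.132 for the falling genes, a difference of -0.084 ± 0.172, while in CPM the same genes gave -0.469 ± 0.222. The log2 enterocyte median was -1.41 in B6 and -0.63 in C5, and the Wnt median 2.10 and 1.19. Since the 2 measures disagree on the same genes, more normal tissue and a weaker tumour response with the donor chromosome cannot be told apart. Gut position stays open too, as Gata4 and Fabp6 differed (above). A biological cause was not tested.

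Chromosome 5 genes were called in both directions between C5 and B6. Reads of the PWD allele could align less often to the C57BL/6 reference, which would lower counts, except where such reads land on a near-identical copy. Being called higher was more frequent on chromosome 5 than elsewhere (17.2 against 9.76% of genes, odds ratio 1.92, 95% interval 1.58 to 2.31), which argues against alignment as the cause for those genes as a set, while single ones with near-identical copies stay open. For the genes called lower (15.8 against 7.89%) the median change on chromosome 5 was -0.0123 relative to other chromosomes (-0.05 to 0.03), which decides nothing because members went both ways. For these, poorer alignment and a regulatory difference of the donor chromosome cannot be told apart, since no reads were available.

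Xist, which coats the inactive X chromosome, rose with AZA from 0.726 ± 0.619 to 200.2 ± 30.5 CPM in B6 organoids and from 0.618 ± 0.555 to 170.5 ± 6.76 CPM in C5 (SD, n = 2 each). Female cells or RNA mixed into the AZA cultures would lower Y-linked genes. The lower of the medians of 4 Y-linked genes was -0.30 in C5 (-0.53 to -0.07), against -0.07 (-0.30 to 0.16) in B6, so a mixture cannot be told apart from an unmixed culture there. Xist induction in male cells is a candidate, under which X-linked genes would be lower. Their median change minus that of autosomal genes was -0.10 (-0.175 to -0.005 over genes, without the spread between libraries). Of 405 X-linked genes 57 were called higher and 63 lower, against 1939 and 1745 of 12923 autosomal genes.

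Other splits of the same libraries were counted for each number of called genes. For adenoma against Min mucosa over 4 backgrounds 1 of 30 drawn splits, the real one, gave as many as 6172 genes (highest other 2496). This argues against chance, at the smallest share 30 splits allow. For C5 against B6 over 3 tissues 1 of 30, the real one, gave as many as 2542 (highest other 1111). Like the first, these splits ignore pairs. Of 30 splits that move pairs together 2 gave as many (highest other 3137), so chance cannot be excluded. That other split leaves all pairs in place and trades 1 wild-type library, and the next gave 35. Chance also cannot be excluded for Min against wild-type mucosa over 4 backgrounds (1 gene, highest other 5, 2 of 30 splits). For the adenoma mean, 30 splits that part every pair gave at most 3982 genes apart from the real one, in a split that trades 1 pair.

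For the differences of the adenoma effect, splits that move pairs apart gave as many genes in 6 of 30 for C5 (15, highest other 3113) and 6 of 30 for B6xPWD (86, highest other 1693). For C5F1 a real count of 0 is reached by all 30 (highest other 502), which says nothing. Splits that call many more genes than the real one point to a structure of the samples, here the pairs. Moving pairs together leaves 10 splits, too few for a share under 0.05. The highest others were 0 in C5 and 1 in B6xPWD, and with the replicate block on adenoma and Min mucosa alone 403 genes were called in C5 (highest other 0), 518 in B6xPWD (9) and 41 in C5F1 (0).

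For the remaining comparisons the splits are too few for a share under 0.05. With 18 splits AZA called 3818 genes (highest other 0). With 10 splits the values for adenoma against Min mucosa were 3647 in B6 (highest other 0), 2801 in C5F1 (8), 378 in C5 (0) and 2241 in B6xPWD (676). The 4 splits that part every pair gave at most 0 others in B6, C5F1 and C5 and 50 in B6xPWD. For Min against wild-type mucosa they were 71 in B6 (10), and 0 in C5F1 (0), C5 (0) and B6xPWD (3), where all 10 splits give as many because the count is 0. For wild-type mucosa against B6 they were 2560 in PWD (704), 201 in C5 (4), 3 in C5F1 (99) and 1311 in B6xPWD (46). For adenoma against B6 they were 2427 in C5 (0), 66 in C5F1 (0) and 2312 in B6xPWD (171).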

How the results depend on the processing

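The alternatives added after the data were seen are named above, and the others were planned. Without ribosomal genes all 38 comparison values and 212 named genes kept their direction and side of the threshold, and with RLE size factors the 38 comparison values did. The 107 list tests were repeated with RLE, without the filter, with the replicate block and with an estimated correlation, and not under the other alternatives. The cause of the changes below was not tested. The planned replicate block joined adenoma, Min and wild-type mucosa of the same number; the numbers of Min and wild-type mucosa and of the organoids are not shown to pair. It gave 101 genes for C5F1 against B6 adenoma, 81 for the difference of the adenoma effect in C5, 21 for the difference of the AZA effect, 2 for Min mucosa in C5F1 and 4 for its mean, and ended 1 list call (fibroblasts with AZA, 0.0564). The block on adenoma and Min mucosa alone gave 733 for adenoma in C5, and 403, 41 and 518 for the differences in C5, C5F1 and B6xPWD. It changed no other call.

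With only the compared groups the counts were 699 (adenoma, B6xPWD), 951 (AZA, C5), 804 and 351 (B6xPWD against B6 adenoma and wild type), 9 (C5 wild type), 734 and 1 (C5F1 adenoma and wild type), 6, 94 and 19 (differences in B6xPWD, C5 and C5F1), 0, 86 and 4 (Min mucosa in B6, C5F1 and the mean) and 1034 (PWD). With DESeq2 they were 332 (C5 wild type), 222 and 118 (C5F1 adenoma and wild type), 224 and 133 (differences in B6xPWD and C5), 178, 1, 1, 1 and 13 (Min mucosa in B6, B6xPWD, C5, C5F1 and the mean). Without the filter on low counts they were 116 (C5 organoids), 7 (difference in C5), 34 (difference of the AZA effect) and 3 (Min mucosa mean). The correlations of adenoma effects were 0.408 and 0.382 for B6 and B6xPWD with DESeq2 and without the filter, 0.522 and 0.465 for B6 and C5, 0.622 and 0.575 for B6 and C5F1, 0.417 and 0.356 for C5 and B6xPWD, 0.511 and 0.452 for C5F1 and B6xPWD, and 0.545 and 0.472 for C5F1 and C5. Without libraries low in Fabp6 the counts were 753 (C5 wild type), 182 (C5F1 wild type), 14 and 2 (Min mucosa in B6 and the mean) and 919 (PWD), and without those over 60% Rn45s 785, 215, 15 and 4 in the first 4 of these.

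Leaving out 1 library in turn, where an arm of 1 organoid library is assumed to vary like the others, moved 93 values by over 1.5 times or over their spread and left 269 within it. The ranges for adenoma against Min mucosa were 1359 to 2448 in B6xPWD, 192 to 328 in C5 and 1788 to 2453 in C5F1. They were 1149 to 1643 and 1232 to 1927 for AZA in B6 and C5, 1338 to 2739 and 597 to 1564 for B6xPWD adenoma and wild type, 1265 to 1933 and 32 to 728 for C5 adenoma and wild type, 9 to 56 and 2 to 195 for C5F1 adenoma and wild type, 22 to 139 for C5 organoids and 1540 to 2855 for PWD. Differences ranged over 7 to 403 (B6xPWD), 0 to 9 (C5) and 0 to 26 (AZA), and Min mucosa over 0 to 201 (B6), 0 to 3 (C5) and 0 to 8 (mean). The correlations ranged over 0.632 to 0.737 (B6 and C5), 0.773 to 0.815 (B6 and C5F1) and 0.699 to 0.777 (C5F1 and C5), and within their spread over 0.482 to 0.702 (B6 and B6xPWD), 0.542 to 0.720 (C5 and B6xPWD) and 0.612 to 0.763 (C5F1 and B6xPWD). The count over 4 backgrounds stayed within 5864 to 6767, B6 adenoma within 2646 to 3168, C5 over 3 tissues within 1765 to 3193 and AZA within 2927 to 4001.

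Among named genes the changes that reversed were of Apc and Pla2g2a and were called in no setting. Of called lists the colon median in adenoma turned from -0.66 to 0.117 without the filter. Apc in C5 over 3 tissues was -0.0093 with DESeq2 and -0.0123 with RLE, and -0.066 to 0.076 without single libraries. Apc in C5 adenoma was -0.035 without B6 replicate 3 and -0.0083 without C5 replicate 3, and at most 0.203 without others. Apc in PWD was 0.0805 without libraries low in Fabp6, 0.0547 without those over 60% Rn45s, and 0.047 and 0.0068 without B6 replicate 3 and PWD replicate 2, and at least -0.050 without others. Pla2g2a in Min mucosa was -0.0030 without C5F1 Min mucosa replicate 2 and at most 0.180 without others. Of the 76 list calls 72 ended with an estimated correlation and 4 remained, the Wnt, fetal and regenerative, matrix and enteroendocrine lists in adenoma against Min mucosa over 4 backgrounds. RLE ended 3 (BMP and fibroblasts in C5 adenoma, 0.0521 each, and fibroblasts with AZA, 0.0534). No filter ended 4 (BMP 0.0878, fibroblasts 0.0571 and pancreas 0.163 in C5 adenoma, colon in adenoma 0.284) and added 2 in C5 over 3 tissues (interferon and MHC class I, 0.0459 each). Among named genes 62 of the fits without 1 library ended a call and 3 added one, 9 calls ended without libraries low in Fabp6, 5 with only the compared groups, 2 with DESeq2 (Olfm4 at 0.17, and Npy2r with no p) and 1 with RLE (Scarna3a at 0.05), while no filter added 4 calls and only the compared groups 3. Depth limits low genes: with 2726505 counts in the smallest tissue library and up to 72.7% of them Rn45s, a group without counts bounds a fold only against 3 counts.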

Other observations

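All genes here were chosen after their values were seen, and no cause was tested. In adenomas the cytokine Il11, a member of the interleukin 6 family made by stroma, rose by 5.22 on the log2 scale, the elastase Cela1 by 2.69 ± 0.24 and the Notch ligand Jag2 by 1.73, while Cyp2c55 fell by 2.74 and the chemokine Ccl25, which draws T cells to the small intestine, fell by 1.497. In PWD wild-type mucosa the retinol and alcohol dehydrogenase Adh1 was higher than in B6 by 5.07 ± 0.67, the leukotriene synthase Ltc4s by 2.73 and the collagen Col3a1 by 1.23, and the B cell gene Fcrla was lower at -5.09.

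Mmrn1 on chromosome 6 had 0 reads in the 9 B6 tissue libraries and 8 or more in the others. Bglap3, an osteocalcin-like gene on chromosome 3 at 88368616, had 178 to 1071 reads in the 9 C5 tissue libraries, 2 to 23 in B6 and 0 in PWD. In organoids it had 1 read in each B6 control, 224 to 272 in C5 controls, and after AZA 222 to 240 in B6 and 2299 to 4958 in C5. Pkd2 on chromosome 5 at 104453982 had 0 reads in C5 control organoids and 88 to 126 in B6, but 18 to 108 in C5 tissue and 42 to 60 in PWD. Lect2 had 29 to 67 reads in PWD wild-type mucosa.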
